A study of Homo sapiens with 20 samples.

How the data were processed

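RNA of 2 SCLC cell lines, H146 and H524, was measured on 20 Illumina BeadChip arrays, with 5 arrays for each of 4 groups: each line with a scrambled control siRNA (siCtrl) or with 2 pooled siRNA duplexes against PRL (siPRL). Per the labels, 250000 cells per well received 1.5 µL of duplex at 20 µM, RNA was taken 2 days after transfection, and 200 ng of RNA were labelled. Groups and replicate letters follow the labels.

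Per the file headers, the deposited intensity values are the mean bead signal of each of 47323 probes, not normalized; the scanner software and its version are not given in the sources used here. Per the file headers, each intensity comes with a detection p-value of the probe, taken against the negative control beads of its array. A table of the authors' processed intensity values was deposited too. Its column medians lie between 136.593 and 136.651, and each column has the ranks of its own array (rank correlation 1, at most 0.904 with any other), so these values are the array signals after some normalization between arrays; the method is not given in the sources used here. All per-sample columns were used.

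The intensities were corrected and normalized with limma 3.58.1 in R 4.3.3 by neqc, which fits a normal-exponential background with moments estimated from the detection p-values, adds an offset of 16, quantile-normalizes and takes log2. A probe was kept when its detection p was below 0.01 on at least 5 of the 20 arrays, which held for 18655 probes. Probes without a single gene symbol were left out of the gene tests: 17202 had none and 8 had several. Of 30113 probes with 1 symbol, 30074 were found by gene ID in the RefSeq table, which changed 0 symbols. Among detected probes of a gene, the one with the highest mean log2 intensity over all arrays stood for it, which left 11303 genes. Of 2888 genes with several detected probes, 55 had probes past the threshold in opposite directions in H146, 10 in H524 and 144 between the lines. Median raw intensity per array was between 114 and 145.

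One linear model with 4 group means was fitted per gene with limma (lmFit and eBayes; 16 residual and 6.03 prior degrees of freedom), and 5 contrasts were taken: siPRL minus siCtrl in H146, the same in H524, their mean, their difference (H524 minus H146), and H524 minus H146 under siCtrl. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05, at which a gene is said to rise, fall or change. PRL was also tested by a 2-sided exact permutation test of 5 against 5 arrays in each line. Genes past the threshold in both lines were counted by direction and compared with the number that independent lists would share, with Fisher's exact test and correlations over genes.

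The design, the alternatives, the 26 gene lists and the rule for named genes were fixed before the data were examined. The lists were: PRL and lactogenic hormone axis, JAK-STAT target genes, neuroendocrine markers, non-neuroendocrine SCLC markers, interferon response, G1/S and replication, G2/M and mitosis, p53 targets, apoptosis regulators, ER stress response, heat shock, oxidative stress (NRF2) targets, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, MYC targets, histone deacetylases and sirtuins, histone genes, cancer-testis antigens, EMT and mesenchymal genes, other cell types (immune, endothelial, erythroid, epithelial), RNA interference machinery, reference (housekeeping) genes, neuronal differentiation, and lung cancer growth factor receptors. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry, adjusted over the 26 lists. Members past the threshold were counted over all genes, and again with p adjusted over the members of the list alone.

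Named genes were PRL and PRLR; for each siPRL contrast and the mean, the 10 largest changes past the threshold in each direction; for the difference, the 6 largest; between the lines, the 10 largest; for each list past the threshold, and always for the interferon, JAK-STAT, neuroendocrine and p53 lists, up to 4 members with the smallest p; and the 10 genes with the largest absolute mean effect among those called in both lines. Probes with placeholder names were passed over.

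For a gene detected on 0 of the 5 arrays of one group, a fitted change rests on a probe at background and is not read as a size; where the groups compared differ in detection in this way, a bound is given. The bound "at least N-fold" sets the mean log2 of the group with signal against the mean, over the arrays of the other group, of the higher of the probe's own value and the lowest normalized signal among probes detected on that array.

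The fit and the list test were run on simulated log2 values with 11303 genes and 200 changed genes. Background correction, normalization and the probe filter were not part of this test. Of genes changed 1.5-fold, 72% were recovered in H146, 48% in H524 and 24% for the difference; at 2-fold it was 100%, 100% and 80%. Calls without a simulated change were 5 of 155, 2 of 66 and 2 of 54. A raised list of 30 genes (log2 shift 0.3) was found and 0 of 25 unchanged lists were. The simulated noise was independent between genes, whereas neuroendocrine markers had an estimated inter-gene correlation of 0.474 in the data. False calls of correlated lists were therefore not tested. In H146 5985 genes changed, so that the recovery rates need not hold for the data.

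Alternatives changed one choice at a time: no background correction with quantile normalization, cyclic loess, median scaling, the authors' processed values, an offset of 50, no filter, detection on all 5 arrays of at least one group, every detected probe, eBayes with trend and robust, array weights, the replicate letter as a block within each line or over both lines, only the arrays compared, an adjusted p below 0.01, at least 1.5-fold, and leaving out each array in turn. The slide as a block could not be tried because the files give no slide. One further alternative, leaving out 3 arrays, was added after the data were seen. The counts of genes were also set against 100 random splits of the arrays per comparison, drawn with a fixed seed. The files give no slide or date, so that batches could not be examined.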

Results

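Transcript levels were measured on 20 Illumina BeadChip arrays in 2 human small cell lung carcinoma (SCLC) lines, H146 and H524. SCLC is a neuroendocrine lung tumour, and both lines grew in suspension and express PRL, the gene of the hormone prolactin. Cells received a scrambled control siRNA (siCtrl) or 2 pooled siRNA duplexes against PRL (siPRL), and were harvested 2 days later. Each of the 4 groups held 5 arrays, replicates A to E. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples. The share of probes detected on an array averaged 36.1% ± 0.855 (SD, n = 5) in H146 siCtrl, 34.1% ± 0.578 in H146 siPRL, 33.1% ± 0.530 in H524 siCtrl and 33.3% ± 1.33 in H524 siPRL. Replicates of a group correlated at r = 0.982 to 0.996 across genes, which are not independent replicates, and the median SD per gene was at most 0.194 on the log2 scale in a group. The number of arrays limits the precision. The first principal component held 82.0% of the variance and separated the lines; the second held 9.40%.

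PRL, the target, was lower in both lines after siPRL. Its probe (ILMN_1809352) was detected on all 20 arrays. In H146 its log2 intensity was 9.25 ± 0.19 (SD, n = 5) with siCtrl and 6.53 ± 0.63 with siPRL, a 6.60-fold lower level that left 15.2% of the control signal. In H524 it was 8.79 ± 0.19 and 6.82 ± 0.27, a 3.91-fold lower level that left 25.6%. The change was -2.72 (SE 0.21, limma adjusted p = 3.38e-10) in H146 and -1.97 (SE 0.21, adjusted p = 6.80e-07) in H524. The 2-sided exact permutation p was 0.00794 in each line, the smallest that 5 against 5 arrays can give. The size of the fall rests on the background correction: without it the change was -1.81 in H146 and -1.31 in H524. H146 siPRL replicate E stood at 7.64, while the other 4 arrays of its group lay between 6.13 and 6.40. The PRL effect was 0.75 weaker in H524 on the log2 scale (adjusted p = 0.0605), and this difference passed the threshold without H146 siPRL replicate E (1.03, adjusted p = 0.000218) and without H524 siPRL replicate A (0.83, adjusted p = 0.0467). The difference of the PRL effect also passed with the replicate letter as a block within each line (adjusted p = 0.0262) or over both lines (0.0474), without background correction (0.0241), with the authors' values (0.0240), an offset of 50 (0.0331), trend and robust (0.0425) or array weights (0.00109). It did not pass with cyclic loess, median scaling, no filter, every detected probe or detection on all arrays of a group. Leaving out any other single array did not bring it past the threshold either. The difference was nearly the same without background correction (0.499) and with the authors' values (0.503), so these are not separate support. Under siCtrl, PRL was -0.46 in H524 relative to H146 (adjusted p = 0.0509), and it passed without H146 siCtrl replicate B (0.0495) or D (0.0467), H146 siPRL replicate C (0.0486), D (0.0476) or E (0.00223), or H524 siCtrl replicate B (0.0427). PRL between the lines also passed without background correction (0.00519), with the authors' values (0.00518), an offset of 50 (0.0162), cyclic loess (0.0393), median scaling (0.0286), detection on all arrays of a group (0.0485), trend and robust (0.0371), array weights (0.00892), the replicate letter as a block over both lines (0.0395) and only the arrays compared (0.00207). PRL between the lines did not pass with no filter, with every detected probe or without any other single array. PRLR, the prolactin receptor gene, has 2 probes (ILMN_1669781 and ILMN_2175236), which were detected on 0 arrays; the smallest detection p was 0.0156.

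**Figure D1:**
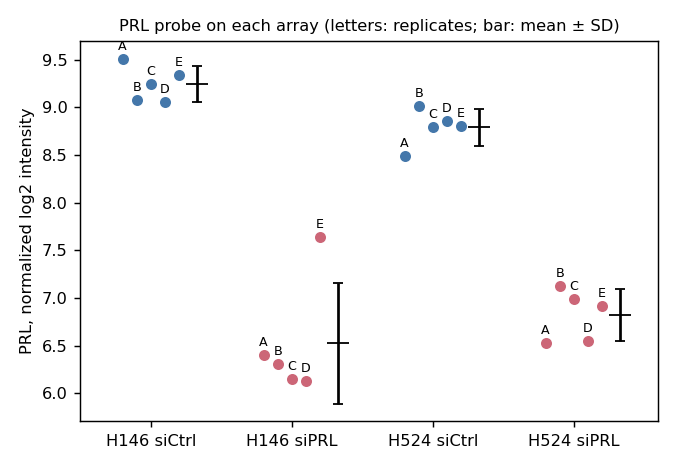
Normalized log2 intensity of the PRL probe on each array, with letters for replicates and bars for the mean ± SD of the 5 arrays of a group. All siPRL arrays lie below all siCtrl arrays of the same line, and H146 siPRL replicate E, at 7.64, lies above the other 4 arrays of its group.

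In H146, groups of replication genes, MYC targets and JAK-STAT target genes were higher after siPRL with camera's preset correlation, and none of these shifts passed with an estimated correlation. The comparison asked which transcripts follow PRL depletion in this line. TRIAP1, a p53-induced inhibitor of apoptosis, rose 7.83-fold (log2 2.97, SE 0.12, limma adjusted p = 2.70e-14). MT1E, a metal-binding metallothionein, fell by 3.43 (SE 0.20, adjusted p = 6.77e-12). PTBP2, a regulator of neuronal splicing, fell by 3.20 (SE 0.12, adjusted p = 1.33e-14).

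Of 11303 genes tested in H146, 5985 (52.95%) changed, 2831 higher and 3154 lower (2510 and 3457 with cyclic loess). A change of at least 2-fold was reached by 1048 of them, 421 higher and 627 lower. After TRIAP1, the genes that rose most were POLR1H, a subunit of RNA polymerase I (log2 2.65), the kinase UHMK1 (2.65), KIFBP, a kinesin-binding protein (2.58), INSIG1, a sterol-regulated brake on cholesterol synthesis (2.56), and the retinol dehydrogenase RDH10 (2.55). HMGB1, a chromatin protein, followed with 2.48, FOSB, a subunit of the AP-1 transcription factor, with 2.46, RPAIN with 2.44 and the splicing factor PRPF31 with 2.41. Their standard errors were 0.09 to 0.19. After MT1E and PTBP2, the genes that fell most were KLHL5 (-2.94), PDLIM7, a PDZ and LIM domain protein of the actin cytoskeleton (-2.90), the tetraspanin TSPAN18, PRL itself, CCDC92 (-2.62), RAI14 (-2.60), GALNT1, which starts mucin-type glycosylation (-2.57; detected on 1 of 5 siPRL arrays), and RCN2 (-2.51). TSPAN18 was detected on none of the siPRL arrays in H146, so that only a bound can be given, at least 3.98-fold lower, and its place among these genes is not certain. The siPRL arrays of H146 also detected fewer probes than the siCtrl arrays (34.1% against 36.1%).

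Of the 26 gene groups, 4 shifted in H146, toward higher levels. Of 30 genes of G1/S and replication, 17 rose and 4 fell (17 and 5 adjusted over the list alone; camera adjusted p = 0.00771, but adjusted p = 0.208 with an estimated correlation). CDC25A, a phosphatase that opens S phase, rose by 1.48 (SE 0.14), the histone chaperone subunit CHAF1A by 1.30, GINS3 of the replicative helicase by 1.17 and the primase subunit PRIM1 by 1.15. Of 28 MYC targets, 17 rose and 2 fell (17 and 2 adjusted over the list alone; adjusted p = 0.00771, but adjusted p = 0.233 with an estimated correlation), with RRP9 at 1.34, the folate carrier SLC19A1 at 1.24, MYBBP1A at 0.82 and NOP16 at 0.77. Of 12 JAK-STAT target genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0432, but adjusted p = 0.208 with an estimated correlation). CCND1, the cyclin of early G1, rose by 1.53 (SE 0.12), MCL1, an anti-apoptotic BCL2 relative, by 1.33, the kinase PIM2 by 0.94 and JUNB by 0.68. Of 37 genes of oxidative phosphorylation, 11 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 0.0432, but adjusted p = 0.233 with an estimated correlation). SDHD, an anchor of succinate dehydrogenase, rose by 1.23, UQCRC2 by 0.94, NDUFA6 by 0.53 and COX6A1 by 0.53. The median change of these 37 genes was 0.11, and 26 of them did not change. For comparison, 2831 of all 11303 genes rose in H146 and 3154 fell. The JAK-STAT call was lost without H146 siCtrl replicate D (0.0580). The oxidative phosphorylation call was lost without H146 siCtrl replicate A (0.0774), B (0.0598), C (0.0565) or D (0.0580), and without siPRL replicate A (0.0552) or D (0.0578).

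The other 22 groups did not shift past the threshold in H146. Of 26 neuroendocrine markers, 2 rose and 9 fell (adjusted p = 0.252). SYT1, the calcium sensor of vesicle release, fell by 2.29 (SE 0.22), SNAP25, a SNARE protein, by 1.76, STMN2 by 0.80 and the receptor kinase RET by 0.77. Without H146 siPRL replicate E the neuroendocrine group passed, lower, with adjusted p = 0.00880; over all arrays it had adjusted p = 0.858 with an estimated correlation. Of 16 interferon response genes, 0 rose and 7 fell (adjusted p = 0.272); IRF7 fell by 0.82, IFIT1 by 0.70, IRF9 by 0.67 and EIF2AK2 by 0.38. Of 18 p53 targets, 7 rose and 5 fell (adjusted p = 0.711). Beside TRIAP1, GADD45B rose by 0.95, while RRM2B, a ribonucleotide reductase subunit, fell by 1.37 and GADD45A fell by 0.67. Of 25 apoptosis regulators, 10 rose and 3 fell (adjusted p = 0.152), and of 18 genes of cholesterol synthesis, 10 rose and 3 fell (adjusted p = 0.0964).

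For the remaining groups in H146 the members that rose and fell were 0 and 2 of 8 in the PRL and lactogenic hormone axis, 4 and 6 of 13 non-neuroendocrine SCLC markers, 9 and 13 of 31 genes of G2/M and mitosis, and 7 and 8 of 24 ER stress genes. They were 3 and 4 of 17 heat shock genes, 4 and 6 of 16 NRF2 targets, 5 and 8 of 28 genes of hypoxia and glycolysis, and 9 and 3 of 44 ribosomal proteins. Histone deacetylases and sirtuins had 2 and 4 of 14, histone genes 4 and 4 of 20, cancer-testis antigens 5 and 4 of 17, and EMT and mesenchymal genes 1 and 6 of 16. The RNA interference machinery had 4 and 5 of 12, reference (housekeeping) genes 4 and 4 of 14, neuronal differentiation genes 0 and 7 of 21, and growth factor receptors of lung cancer 2 and 6 of 11. Of 5 detected markers of other cell types (immune, endothelial, erythroid or epithelial), 0 rose and 1 fell. Adjusted over the list alone, the counts of the 22 groups were unchanged except for p53 targets (7 and 6), ribosomal proteins (7 and 3), histone deacetylases and sirtuins (2 and 3) and neuronal differentiation genes (0 and 5).

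In H524, genes of mitosis were lower after siPRL, and fewer genes changed than in H146. Histone genes were lower too with camera's preset correlation, but not with an estimated correlation (adjusted p = 0.393). The comparison asked the same question in the other line. MT1G, a metallothionein detected on 2 of 5 siPRL arrays, fell by 2.37 (SE 0.17, limma adjusted p = 4.22e-09). OVOL2, a zinc finger factor of epithelial cells, rose 3.63-fold (log2 1.86, SE 0.21, adjusted p = 1.51e-06). MTHFD2, a mitochondrial enzyme of one-carbon metabolism, rose 2.98-fold (log2 1.58, SE 0.13, adjusted p = 3.03e-08).

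Of the 11303 genes, 2485 (22.0%) changed in H524, 1225 higher and 1260 lower, and 137 of them at least 2-fold, 61 higher and 76 lower. After OVOL2 and MTHFD2 the genes that rose most were SUSD2 (log2 1.50, SE 0.37), PLIN3, a lipid droplet coat protein (1.34), POLR1H (1.34), ZMYM6 (1.34), KIFBP (1.33), the homeobox factor HOXC8 (1.33), the mitochondrial carrier SLC25A44 (1.33) and the potassium channel subunit KCNS3 (1.32). After MT1G the genes that fell most were XYLT1, which starts glycosaminoglycan chains (-1.99; detected on 1 of 5 siPRL arrays), PRL, SYT1 (-1.97), CLSTN2 (-1.82), MT1F (-1.81), DYM (-1.69), MT1H, the RNA-binding protein RBM24 (-1.61) and the small nucleolar RNA SNORD13 (-1.59). MT1H was detected on none of the H524 siPRL arrays, so that only a bound can be given, at least 1.56-fold lower, and its place among these genes is not certain. The probes of metallothionein genes can share signal, since these genes are near-identical in sequence.

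Of 31 genes of G2/M and mitosis in H524, 4 rose and 20 fell (4 and 21 adjusted over the list alone; camera adjusted p = 1.48e-05, and adjusted p = 0.000849 with an estimated correlation). MAD2L1 of the spindle checkpoint fell by 0.99 (SE 0.14), the checkpoint kinase TTK by 0.63 and CDK1, the kinase that drives entry into mitosis, by 0.57. PLK1, a mitotic kinase, went the other way and rose by 1.09 (SE 0.14). Of 20 histone genes, 0 rose and 10 fell (0 and 12 adjusted over the list alone; adjusted p = 6.88e-05, but adjusted p = 0.393 with an estimated correlation), with H2AC18 at -0.77, H2BC5 at -0.69, H2BC11 at -0.68 and H3-3B at -0.46. Of 26 neuroendocrine markers, 3 rose and 7 fell (adjusted p = 0.0985). SYT1 fell by 1.97, SNAP25 by 1.34 and STMN2 by 0.85, while CHGA, which encodes chromogranin A, rose by 0.74. Without H146 siPRL replicate E, which enters the shared estimate of the spread, the neuroendocrine group passed, lower, with adjusted p = 0.0276, and it passed with no filter on probes (0.0464). Over all arrays it had adjusted p = 0.759 with an estimated correlation.

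The other 24 groups did not shift past the threshold in H524. Of 16 interferon response genes, 0 rose and 0 fell; the 4 with the smallest p were USP18 (0.51, adjusted p = 0.0582), IRF9 (0.27, 0.0702), IFI6 (0.27, 0.196) and OAS3 (adjusted p = 0.268; detected on 0 H524 arrays). USP18 passed without H146 siPRL replicate D (0.0494) or E (0.0317), H524 siCtrl replicate A (0.0171) or H524 siPRL replicate E (0.0292), with the replicate letter as a block within each line (0.00605) or over both lines (0.0383), with array weights (0.0198) and with trend and robust (0.0487). IRF9 passed without H146 siPRL replicate E (0.0336) or H524 siCtrl replicate C (0.0389), without background correction (0.0301), with the authors' values (0.0297) and with an offset of 50 (0.0497), and IFI6 passed without H524 siCtrl replicate A (0.0128). Of 18 p53 targets, 2 rose and 1 fell: TRIAP1 rose by 1.18 and CDKN1A, which encodes the cell cycle inhibitor p21, fell by 0.84. XPC stood at -0.25 (adjusted p = 0.0645; 0.0342 without H146 siPRL replicate E and 0.0352 without H524 siCtrl replicate C). TNFRSF10B, a TRAIL receptor, passed at 0.48 (adjusted p = 0.0355), and missed the threshold without H524 siCtrl replicate B (0.103), C (0.0611) or E (0.100) or siPRL replicate A (0.112) or B (0.0752). TNFRSF10B also missed it without background correction (0.0682), with the authors' values (0.0677), median scaling (0.0504), no filter (0.0586), array weights (0.0523) and only the arrays compared (0.0827). Of 12 JAK-STAT target genes, 4 rose and 2 fell, with PIM2 at 0.61, CCND1 at 0.54, PIM1 at -0.83 and BCL6 at -0.75.

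Of the remaining groups in H524, G1/S and replication had 1 member that rose and 5 that fell, MYC targets 2 and 2, oxidative phosphorylation 2 and 0, apoptosis regulators 7 and 3, and cholesterol synthesis 5 and 2. No more than 4 members rose or fell in any of the others. Adjusted over the list alone the counts differed for MYC targets (0 and 2), oxidative phosphorylation (1 and 0), ribosomal proteins (0 and 0, from 1 and 0), cholesterol synthesis (6 and 3), EMT and mesenchymal genes (2 and 2, from 2 and 1) and the RNA interference machinery (2 and 3, from 1 and 3). Where median, mean and test of a group differed in sign, in H146 or H524, the group was not past the threshold.

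**Figure D2:**
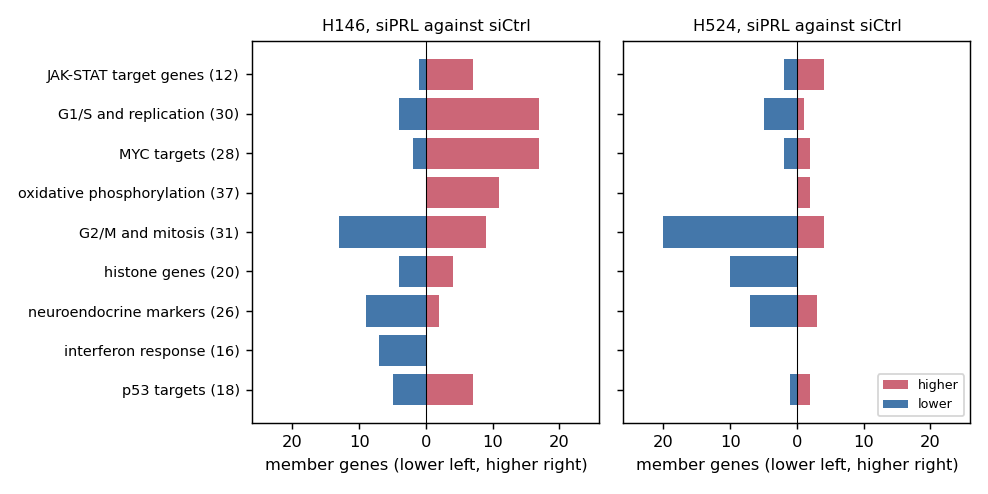
Number of member genes past an adjusted p of 0.05 in 9 gene groups, higher to the right and lower to the left, in H146 and H524; the number of tested members stands in parentheses. G1/S and replication has 17 higher members in H146 and 1 in H524, and G2/M and mitosis has 20 lower members in H524.

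Averaged over the 2 lines, TRIAP1, POLR1H, KIFBP and UHMK1 led the transcripts that rose after siPRL, and PRL, PTBP2, MT1E and SYT1 led those that fell. This comparison asked which transcripts respond on average. TRIAP1 rose 4.22-fold (log2 2.08, SE 0.08, limma adjusted p = 2.18e-14) and PTBP2 fell by 2.29 (SE 0.08, adjusted p = 6.92e-15). Of the 11303 genes, 5939 changed on average, 2828 higher and 3111 lower, and 343 of them at least 2-fold. POLR1H stood at 2.00, KIFBP at 1.95, UHMK1 at 1.94, MTHFD2 at 1.86, INSIG1 at 1.85, PRPF31 at 1.81, ESYT2 at 1.66, HMGB1 at 1.66 and CMTM3 at 1.64. Among the lower genes PRL stood at -2.34, MT1E at -2.25, SYT1 at -2.13, CLSTN2 at -2.002, DYM, GALNT1 and FAM3C at -1.99, -1.95 and -1.95, RCN2 at -1.88 and MT1G at -1.83. CLSTN2 and GALNT1 were detected on 1 of 5 H146 siPRL arrays, which limits the precision of their means.

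None of the 26 groups passed for the mean effect; the smallest camera adjusted p was 0.0932, for MYC targets, of which 15 rose and 2 fell (15 and 2 adjusted over the list alone). Of 26 neuroendocrine markers 3 rose and 10 fell (3 and 10 adjusted over the list alone; adjusted p = 0.129), with SNAP25 at -1.55, STMN2 at -0.82 and CHGA at 0.73. Without H146 siPRL replicate E this group passed, lower, with adjusted p = 0.0129, and with no filter on probes with 0.0427. Over all arrays it had adjusted p = 0.765 with an estimated correlation. Of 12 JAK-STAT target genes 6 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 0.116), with CCND1 at 1.03, PIM2 at 0.77, MCL1 at 0.70 and PIM1 at -0.85. Of 18 p53 targets 6 rose and 4 fell (6 and 5 adjusted over the list alone; adjusted p = 0.724), with TNFRSF10B at 0.74, CDKN1A at -0.76 and RRM2B at -0.62. Of 16 interferon response genes 0 rose and 5 fell (0 and 3 adjusted over the list alone; adjusted p = 0.576). IRF9 fell by 0.20; IRF7, IFIT1 and OAS3 passed too, but were detected on 0 H524 arrays, so that their mean has no certain size. The IRF9 call was lost without H524 siCtrl replicate C (0.0589) or D (0.0530), without background correction (0.0501) and with the authors' values (0.0510).

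The genes that changed in both lines mostly moved the same way. The overlap addressed whether the lines responded alike. A total of 876 genes were higher in both lines, where independent lists would share 306.8, and 903 were lower in both, against 351.6. Only 91 went in opposite directions, against 657 for independent lists. Fisher's exact test over genes, which are not independent replicates, gave an odds ratio of 10.4 for the higher and 8.75 for the lower genes (p = 4.74e-294 and 1.68e-261). The lines shared no control arrays. Of the H524 calls, 71.6% were also made in H146 in the same direction. Across the 11303 genes the log2 fold changes correlated at Pearson r = 0.600 and Spearman rho = 0.548, and the slope of H524 on H146 was 0.323. Of the 1779 genes that changed the same way in both lines, 1450 had the smaller effect in H524, and for 674 the difference itself passed the threshold. The shared genes of largest mean effect were PRL, PTBP2, MT1E, SYT1, CLSTN2, DYM and GALNT1 among the lower and TRIAP1, POLR1H and KIFBP among the higher.

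**Figure D3:**
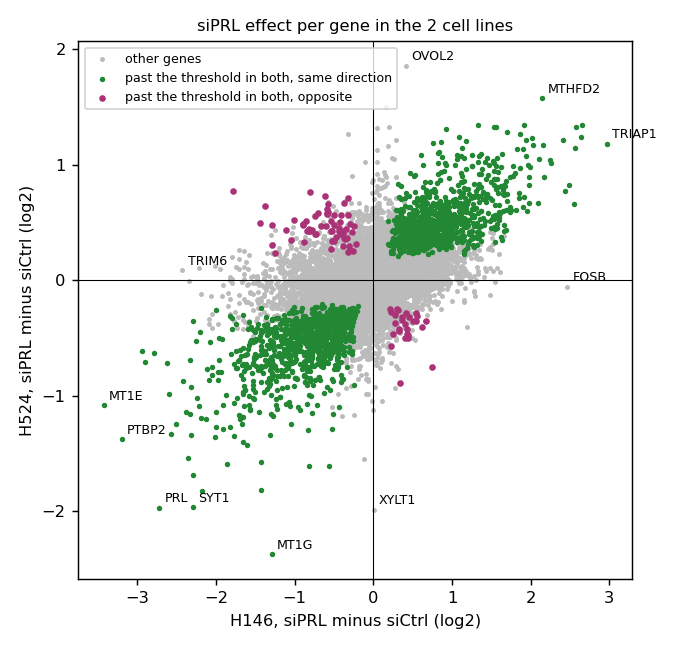
siPRL effect (log2, siPRL minus siCtrl) of each of 11303 genes in H146 on the horizontal and in H524 on the vertical axis. Points for the 1779 genes past the threshold in both lines in the same direction lie in the lower left and upper right, and 91 genes moved in opposite directions.

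The siPRL effect was lower in H524 than in H146 for genes of replication and mitosis and for JAK-STAT target genes, among others. Effects were mostly smaller in H524 (slope 0.323 across genes), so a group that rose in H146 can differ through a weaker response alone. This applies to JAK-STAT target genes (median 0.49 in H146, 0.13 in H524), MYC targets (0.33, 0.05) and oxidative phosphorylation (0.11, 0.01). The median changed sign for replication genes (0.27, -0.10) and was lower in H524 for mitosis genes (-0.17, -0.35). This comparison tested the difference of the effects itself, H524 minus H146. For CDC25A the difference was -1.61 (SE 0.20, limma adjusted p = 3.90e-06), and for CDK1 -0.79 (SE 0.12, adjusted p = 4.47e-05). For MCL1, which rose in H146, it was -1.254 (SE 0.11, adjusted p = 8.04e-08).

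The difference passed the threshold for 3120 of 11303 genes, of which 1689 had the higher effect in H524 and 1431 the lower. The balance of directions depends on the scaling: with cyclic loess it was 1852 and 1146. Among the fitted differences furthest from 0 were those of MT1E (2.34) and KLHL5 (2.33), with the higher effect in H524, and of RDH10 (-1.89), TRIAP1 (-1.79), RPAIN (-1.66) and HMGB1 (-1.66), with the lower. ARSD, TRIM6, GPER1, the nuclear receptor PPARG, FOSB and XYLT1 passed too, but lacked signal in part of the comparison, so that their differences have no certain size. TRIM6, GPER1, PPARG and FOSB were detected on 0 H524 arrays, XYLT1 on 0 H146 arrays and ARSD on 0 H524 siCtrl arrays. The GPER1 call was lost when no probe was filtered out (0.33, adjusted p = 0.501).

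Of 30 genes of G1/S and replication, 1 had a higher and 13 a lower effect in H524 (1 and 17 adjusted over the list alone; camera adjusted p = 2.90e-07, and adjusted p = 0.0280 with an estimated correlation). CHAF1A differed by -1.43, GINS3 by -1.23 and PRIM1 by -0.999. Of 12 JAK-STAT target genes, 1 was higher and 5 were lower (1 and 5 adjusted over the list alone; adjusted p = 0.0171, and adjusted p = 0.0425 with an estimated correlation), with BCL6 at -1.03, CCND1 at -0.998 and STAT3 at 0.65. Of 31 genes of G2/M and mitosis, 1 was higher and 8 were lower (1 and 8 adjusted over the list alone; adjusted p = 0.0199, and adjusted p = 0.0425 with an estimated correlation). UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, differed by -1.01, BUB1B by -0.95 and PRC1 by -0.55. Of 28 MYC targets, 0 were higher and 11 lower (0 and 13 adjusted over the list alone; adjusted p = 0.00254, but adjusted p = 0.179 with an estimated correlation), with SLC19A1 at -1.05, RRP9 at -1.02, NOP16 at -0.89 and DKC1 at -0.40. Of 37 genes of oxidative phosphorylation, 0 were higher and 7 lower (0 and 5 adjusted over the list alone; adjusted p = 0.0199, but adjusted p = 0.179 with an estimated correlation), with SDHD at -0.65, UQCRC2 at -0.60 and NDUFA6 at -0.37; UQCRB passed too, but has probes past the threshold in opposite directions in H146 and between the lines.

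The other 21 groups did not differ past the threshold. Of 16 interferon response genes 5 had the higher effect in H524 and 0 the lower (5 and 0 adjusted over the list alone; adjusted p = 0.109), with IRF9 at 0.94 and EIF2AK2 at 0.53; IFIT1 and IRF7 passed too, but were detected on 0 H524 arrays. Of 18 p53 targets 3 were higher and 5 lower (3 and 5 adjusted over the list alone; adjusted p = 0.582), with RRM2B at 1.50, GADD45A at 0.79, and with GADD45B, which passed but was detected on 0 H524 arrays. Of 26 neuroendocrine markers 1 was higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.804): RET, which was detected on 0 H524 arrays. CPE (0.50, adjusted p = 0.0746), INSM1 (-0.46, 0.0925) and CALCB (adjusted p = 0.147; detected on 0 H146 arrays) did not pass. CPE passed without H146 siPRL replicate E (0.000834), with trend and robust (0.0475) and with array weights (0.00265), INSM1 without H146 siPRL replicate A (0.0338) and CALCB without H524 siCtrl replicate A (0.0374).

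Under siCtrl the lines differed in most of their transcripts, and non-neuroendocrine markers, cancer-testis antigens and growth factor receptors were lower in H524 with camera's preset correlation. None of these group shifts passed with an estimated correlation. This comparison describes the background in which PRL was depleted. SNTB1, a syntrophin, was at least 587-fold higher in H524, and NKX2-1, a lung lineage factor, at least 56.1-fold higher. DKK1, a secreted WNT inhibitor, was at least 176-fold lower in H524 and the neuropeptide gene NTS at least 142-fold lower. These bounds stand where one line detected the probe on none of its 5 siCtrl arrays.

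Of the 11303 genes, 8676 (76.8%) differed, 4442 higher in H524 and 4234 lower, and 3707 by at least 2-fold. Which direction held more genes depends on the scaling: with cyclic loess 3937 were higher and 4685 lower, and with median scaling 3869 and 4450. OLFM1 was at least 110-fold, NEFM at least 81.1-fold, STC1 at least 63.7-fold, OTX2 at least 61.1-fold, CCND2 at least 58.5-fold and NPTX2 at least 56.0-fold higher in H524, and REC8 (log2 6.73, SE 0.17, limma adjusted p = 6.90e-20) and NDN were higher too; NDN was detected on 2 of 5 H146 siCtrl arrays, so that its difference has no certain size. Lower in H524 were AKR1C2 (at least 130-fold), ANXA1 (at least 115-fold), CLDN18 (at least 105-fold), CAV1 (at least 91.1-fold), SCG2 (at least 77.9-fold), MAGEB2 (at least 66.2-fold), FOXA2 (at least 64.6-fold) and IFITM2, which was detected on 1 of 5 H524 siCtrl arrays, so that its difference has no certain size.

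Of the 26 gene groups, 8 shifted between the lines with camera's preset correlation, and 0 with an estimated one. Of 13 non-neuroendocrine SCLC markers, 1 was higher and 12 lower in H524 (1 and 12 adjusted over the list alone; adjusted p = 1.52e-05, but adjusted p = 0.127 with an estimated correlation); beside ANXA1 and CAV1, LGALS1 stood at -6.83 and S100A10 at -4.72. Of 17 cancer-testis antigens, 1 was higher and 16 lower (1 and 16 adjusted over the list alone; adjusted p = 5.61e-07, but adjusted p = 0.107 with an estimated correlation), with MAGEC2 at least 29.0-fold, PAGE2 at least 15.0-fold and MAGEA12 at least 13.0-fold lower. Of 11 growth factor receptors and ligands, 1 was higher and 7 lower (1 and 7 adjusted over the list alone; adjusted p = 0.0240, but adjusted p = 0.127 with an estimated correlation), with KITLG at least 29.0-fold lower, ERBB3 at least 3.52-fold lower, RET at least 3.39-fold lower and ERBB2 at -2.70. That call was lost with no filter on probes (0.0533). Of 17 heat shock genes, 2 were higher and 12 lower (2 and 12 adjusted over the list alone; adjusted p = 0.0194, but adjusted p = 0.127 with an estimated correlation), with the co-chaperone BAG3 at -4.30, HSPB1 at -2.91, DNAJB1 at -1.45 and HSPH1 at 1.68; under median scaling the call was lost (0.0868). Of 16 interferon response genes, 3 were higher and 11 lower (3 and 11 adjusted over the list alone; adjusted p = 0.0447, but adjusted p = 0.127 with an estimated correlation), with ISG15 at least 50.3-fold lower, IFIT1 at least 6.36-fold lower, ISG20 at -2.34 and IFI44, detected on 1 of 5 H146 siCtrl arrays, higher. This call was lost without H524 siPRL replicate A (0.0510), without background correction (0.0644), with the authors' values (0.0642), with an offset of 50 (0.0571), after cyclic loess (0.0602) and with detection required on all arrays of a group (0.0572).

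The other 3 groups were higher in H524 under siCtrl. Of 30 genes of G1/S and replication, 19 were higher and 3 lower (19 and 3 adjusted over the list alone; adjusted p = 0.0159, but adjusted p = 0.131 with an estimated correlation), with GINS3 at 1.97, CDC45 at 1.71, MCM4 at 1.52 and POLA1 at 1.13. Of 28 MYC targets, 20 were higher and 5 lower (20 and 5 adjusted over the list alone; adjusted p = 0.0205, but adjusted p = 0.239 with an estimated correlation), with RRP9 at 2.24, SLC19A1 at 1.84, MYBBP1A at 1.46 and DKC1 at 1.33. Of 20 histone genes, 12 were higher and 5 lower (12 and 5 adjusted over the list alone; adjusted p = 0.0447, but adjusted p = 0.430 with an estimated correlation), with H2AC25 at 2.45, H2AC20 at 1.79, H2AJ at 1.78 and H2BC12 at 1.37. The histone call was lost without H146 siCtrl replicate A (0.0515) or E (0.0546). Of 26 neuroendocrine markers, 15 were higher and 9 lower (16 and 9 adjusted over the list alone; adjusted p = 0.607); GRP was at least 42.0-fold lower in H524. Of 18 p53 targets, 4 were higher and 10 lower (4 and 10 adjusted over the list alone; adjusted p = 0.109, but 0.0435 with no filter on probes), with TNFRSF10B at -2.57, GADD45A at -2.20, PMAIP1 at -1.92 and PHLDA3 at least 1.28-fold lower. Of 12 JAK-STAT target genes, 4 were higher and 4 lower (4 and 4 adjusted over the list alone; adjusted p = 0.870), with MYC at 1.81, BCL6 at -1.17, IRF1 at -1.80 and SOCS2 at -3.33.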

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

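The tests of an intensity-dependent difference after cyclic loess, of the intensity trend shared by the lines, of direct silencing, and the setting without 3 arrays were chosen after the results were seen.

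The siPRL response in H146 was broad, with 5985 of 11303 genes past the threshold. Of 100 splits of the 10 arrays into 5 and 5, 1 called as many genes, the real one. It called 6014 genes in a fit of these arrays, against at most 1 in another split. A random split of these arrays thus does not give such a count. The splits cannot separate the siRNAs from a culture or batch shared by the arrays of a group, which the labels do not give. Cyclic loess left 94.3% of the genes called in the same direction. It took the place of quantile normalization, which also evens out intensity trends between arrays. The share therefore does not decide on an intensity-dependent difference between the arrays. With genes in 3 equal sets by mean intensity, the share called was 60.5% in the brightest set and 39.4% in the dimmest. The changes were thus not confined to dim genes. In H524, where siPRL arrays detected 33.3% of probes and siCtrl arrays 33.1%, the shares were 25.1% and 14.5%. Bright genes were called more often in both lines, so that the shares do not decide on a loss of dim transcripts in H146. A response to less PRL and a response to the siRNA duplexes themselves stay open, since each line had 1 PRL siRNA pool and 1 scrambled control.

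The lines shared much of their response (r = 0.600 across genes). Of 100 draws of the siRNA labels within each line, 1 gave a correlation as far from 0, the real one, against 0.550 in the next highest. A draw that keeps or swaps most labels in both lines carries part of the siPRL response. The draws thus do not show what correlation unrelated responses would give. With a loess on mean intensity taken out of each line, r was still 0.600. The values had already been quantile-normalized, which leaves little intensity trend to take out. This value therefore does not decide on an array trend or batch common to both lines. Higher in both lines were 876 genes, against 307 for independent lists. Direct silencing by the duplexes lowers its targets, so genes picked for being higher are no test of it, and an indirect effect of other silenced transcripts on them stays open. For the 903 genes lower in both, direct silencing and a response to less PRL cannot be told apart, because each line had 1 siRNA pool and no transcript sequences were at hand.

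PRL on H146 siPRL replicate E stood at 7.64, and the other 4 arrays of its group at 6.13 to 6.40. The size of the array's response over the genes that changed over 2-fold on the other 4 arrays was 0.938, and those arrays ranged from 0.909 to 1.03. This argues against a weaker response of the whole array, but PRL was not alone. SYT1, which falls, stood at 7.36 (6.01 to 6.04 on the others). Among genes that rise, RDH10 stood at 9.81 (10.28 to 10.37), CMTM3 at 10.10 (10.53 to 10.65), GADD45B at 6.90 (7.70 to 7.80) and RRP9 at 7.69 (8.26 to 8.30). RPAIN, which rises, went the other way with 11.23 (11.02 to 11.05). Admixture of control RNA would need a share of 23.0% to give this PRL level. The 37 strongly lowered genes lay at -1.02 (SE 0.101) on the log2 scale relative to the level that share predicts, and 36 of them were below it, which argues against admixture. What set PRL and SYT1, RDH10, CMTM3, GADD45B, RRP9 and RPAIN apart on this array stays open. No biological explanation was tested.

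For the other counts of genes, 1 of 100 splits called as many in H524 (2162 genes, at most 4 in another) and between the lines under siCtrl (8874, at most 0 in another). For the mean effect 1 of 100 draws of the labels within lines called as many (5939, next 3940). Random groupings of these arrays thus do not give such counts, but a culture or batch shared by the arrays of a group is not excluded. For the difference 2 of 100 draws called as many (3120, with 4384 in another), but such draws do not model equal effects in both lines, so that their share says nothing on how many effects differ. The draws with 3940 and 4384 genes kept all 10 labels of H146 and 4 of 10 of H524, and so carry the H146 response.

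Among 433 groups of 5 values, 29 had 1 array apart from the other 4 by Dixon's test at a critical value of 0.710, where 1 in 20 groups, 21.65, would be so by chance. In log2 intensity, the values apart from the other 4 of their group were PRL 7.64, CMTM3 10.10, GADD45B 6.90, RDH10 9.81, RPAIN 11.23, RRP9 7.69 and SYT1 7.36 on H146 siPRL replicate E. Further values of this kind were ARSD 5.01, BAG3 7.65, CDC25A 9.44, IFITM2 6.29, SUSD2 10.34 and TTK 10.29 on H524 siCtrl replicate A. Others were CDC25A 9.27, HOXC8 8.35 and SUSD2 11.53 on H524 siPRL replicate A. Apart as well lay EIF2AK2 9.51, KITLG 10.14 and PRC1 11.43 on H146 siCtrl replicate E. Further values of this kind were FOXA2 5.25, SNAP25 10.00 and STAT3 9.33 on H524 siCtrl replicate B. Others were KCNS3 5.13 and RRM2B 5.61 on H524 siCtrl replicate D. Apart as well lay PIM2 7.66 and STMN2 10.24 on H146 siCtrl replicate A. Further values of this kind were POLR1H 6.90 on H146 siCtrl replicate C. Others were RBM24 8.35 on H524 siCtrl replicate C. H146 siPRL replicate B had a median intensity of 129, while the rest of its group lay between 142 and 145. By array, 7 such values fell on H146 siPRL replicate E and 6 on H524 siCtrl replicate A. ARSD and FOXA2 were detected on none of the H524 siCtrl arrays and IFITM2 on 1 of 5, so their values there lay near background.

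The siPRL effect differed between the lines for 3120 genes, and for 71 of the 96 genes named outside the comparison of the lines under siCtrl. Some of the 96 were named for a large difference or a small p in this contrast, so that their share is not representative. Written as the log2 effect in H524 minus that in H146, the positive differences were ARSD 2.55, TRIM6 2.51, MT1E 2.34, GPER1 2.33, KLHL5 2.33, PPARG 2.31, PDLIM7 2.20, TSPAN18 2.15, CCDC92 1.90, PTBP2 1.82, H2BC5 1.64, RAI14 1.62, RRM2B 1.50, OVOL2 1.45, RCN2 1.27, GALNT1 1.23, HOXC8 1.12, IRF9 0.94, FAM3C 0.81, IFIT1 0.79, GADD45A 0.79, USP18 0.78, RET 0.76, IRF7 0.73, STAT3 0.65, DYM 0.61 and EIF2AK2 0.53. The negative differences were FOSB -2.52, XYLT1 -1.99, RDH10 -1.89, TRIAP1 -1.79, RPAIN -1.66, HMGB1 -1.66, CDC25A -1.61, CHAF1A -1.43, INSIG1 -1.42, UHMK1 -1.40, POLR1H -1.30, MCL1 -1.254, KIFBP -1.246, GINS3 -1.23, CMTM3 -1.20, PRPF31 -1.20, H2AC18 -1.08, MT1G -1.08, RBM24 -1.05, SLC19A1 -1.05, BCL6 -1.03, RRP9 -1.02, UBE2C -1.01, PRIM1 -0.999, GADD45B -0.998, CCND1 -0.998, ESYT2 -0.99, BUB1B -0.95, NOP16 -0.89, MT1H -0.80, CDK1 -0.79, SDHD -0.65, H2BC11 -0.62, UQCRC2 -0.60, MTHFD2 -0.57, PRC1 -0.55, UQCRB -0.53, MYBBP1A -0.52, JUNB -0.51, COX6A1 -0.41, DKC1 -0.40, MT1F -0.39, XPC -0.38 and NDUFA6 -0.37. Of these genes, FOSB, TRIM6, GPER1, PPARG, RET, IFIT1, IRF7 and GADD45B were detected on 0 H524 arrays, XYLT1 and RBM24 on 0 H146 arrays, and TSPAN18, MT1H and ARSD on 0 arrays of 1 group, so that their fitted differences rest on probes at background and have no certain size. The median difference of list members was -0.31 for JAK-STAT target genes, -0.32 for G1/S and replication, -0.16 for G2/M and mitosis, -0.11 for oxidative phosphorylation and -0.25 for MYC targets.

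Outside the genes tested, 3801 detected probes had no single gene symbol. Of these, 1277 changed in H146 (701 higher, 576 lower) and 391 in H524 (185 higher, 206 lower).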

How the results depend on the processing

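The setting without H146 siPRL replicate E and H524 siCtrl and siPRL replicates A was chosen after the data were seen.

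Under the stricter thresholds fewer genes passed, by construction. At 1.5-fold the counts were 3005 in H146, 791 in H524, 1493 for the mean, 1968 for the difference and 558 for the overlap; at an adjusted p below 0.01 they were 1477 in H524, 1890 for the difference and 1102 for the overlap. With every detected probe, 13675 probes differed between the lines, since more features were tested. The correlation between the lines was 0.654 without background correction, 0.654 with the authors' processed values and 0.556 with no filter (jackknife SE 0.0440); the cause was not tested.

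Leaving out each array in turn gave 5539 to 6157 genes in H146, 2083 to 2775 in H524, 5633 to 6200 for the mean, 2778 to 3434 for the difference, 8378 to 8770 between the lines, 1545 to 1961 in the overlap and r from 0.578 to 0.617. PRL ranged from -3.00 to -2.62 in H146 and from -2.04 to -1.89 in H524. Without the 3 arrays the counts were 6461, 2706, 6273, 3544 and 8755, with 1964 in the overlap. The size of the PRL change rests on the background: without its correction it was -1.81 and -1.31, with the authors' values -1.82 and -1.32, and with an offset of 50 -2.33 and -1.69.

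Neuroendocrine markers, not past the threshold for the difference, changed sign with median scaling (adjusted p = 0.991) and ranged from 0.0852 to 0.988 as arrays were left out; between the lines the sign changed with fry (adjusted p = 0.123). The cause was not tested. Of 227 named gene results, 217 of them past the threshold, 15 changed side in at least 1 of up to 34 alternatives. The difference lost its call for IRF7 with array weights (adjusted p = 0.0589) and, with median scaling, for EIF2AK2 (0.0598) and NDUFA6 (0.0896).

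Of 26 lists, fry called 20 in H146 (16 not called by camera), 8 in H524 (6), 22 for the mean (22), 13 for the difference (8) and 22 between the lines (14). Among those only fry called in H146 were the reference genes (adjusted p = 0.00734). Unlike camera, fry does not weigh a list against the other genes. For 4 lists the values with fry alone were: in H146 the interferon response, lower (adjusted p = 2.99e-06), and p53 targets, higher (9.01e-06); in H524 JAK-STAT (0.0398) and p53 targets (0.0243), higher; for the mean JAK-STAT (1.04e-09), neuroendocrine (0.0167), interferon (0.000884) and p53 (7.07e-06); for the difference interferon (2.44e-05) and p53 (0.0278); between the lines JAK-STAT (4.55e-08) and p53 (4.32e-15).

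The replicate letter showed no pairing that held across the arrays. The deviations of siCtrl and siPRL arrays of one letter correlated at -0.13, -0.04, -0.02, 0.20 and 0.04 in H146 and at 0.50, 0.08, 0.09, 0.00 and -0.10 in H524, where the own letter was the best partner for A and C. With the letter as a block, 390 gene results and 61 list results were the same and 5 gene results moved past the threshold: the PRL difference and USP18 in H524 in both forms of the block, and PRL between the lines (adjusted p = 0.0395) in the form over both lines. The slide as a block was not run, since the files give none. Signal over background limits the genes near the detection floor, for which a fall could not be measured.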

Other observations

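The tests of metallothioneins, actin cytoskeleton, amino acid starvation and synaptic genes were all chosen after the results were seen. The 4 lists were drawn up after leading genes had been noted. They were tested with all members first, and after those results were known, members whose values had been noted were left out, the verdict rule was rewritten and the tests were run again. Values of both runs are given.

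Metallothioneins bind zinc and copper and are induced by metals. Of 7 tested, 0 rose and 6 fell in each line (camera adjusted p = 0.000123 in H146 and 6.15e-10 in H524; 0.0241 and 0.00121 with an estimated correlation). MT2A fell by 1.60 in H146 and by 1.43 in H524, and MT1X by 1.64 and 1.09, while MT3 was not past the threshold. These directions were the same under cyclic loess and median scaling. The second run left 1 member, MT3, too few to test. MT3 stood at 0.12 in H146 (limma adjusted p = 0.635) and at 0.18 in H524 (0.577). The fall thus covered 6 of the 7 members tested, and a fall of the whole family was not shown. MT1F and MT1G fell more in H524, and MT1E and MT1X fell more in H146, which argues against 1 signal shared completely by all probes. A partial sharing of signal between the probes stays open. MT1H had the larger fitted fall in H524, but was detected on none of the H524 siPRL arrays and gives no support. Counted with MT1H, 3 members fell more in H524 and 2 in H146. With cyclic loess these counts were 2 and 2, and with median scaling 2 and 1.

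Genes of the actin cytoskeleton and focal adhesions were lower in H146, where of 36 tested 5 rose and 26 fell (adjusted p = 2.61e-05; 0.0241 with an estimated correlation), and not in H524 (5 rose, 2 fell; 0.620). The difference between the lines passed (18 higher and 4 lower in H524; 2.14e-08). VCL fell by 1.64, MYL9 by 1.82 and FERMT2 by 2.29 in H146, while CCN2 rose by 1.15. Over the 31 members left in the second run, 5 rose and 21 fell in H146 (adjusted p = 0.00482, but 0.103 with an estimated correlation), and the difference passed (0.000108; 0.0238 with an estimated correlation). A lower level of this programme in H146 may follow the PRL siRNAs, as a hypothesis found and tested on the same arrays.

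Synaptic vesicle and exocytosis genes were lower for the mean of the lines with all 25 members (0 rose, 9 fell; adjusted p = 0.0108, but 0.313 with an estimated correlation), and not past the threshold over the 23 members of the second run (adjusted p = 0.0723). Genes of amino acid starvation and one-carbon metabolism, tested for a higher mean level, were past the threshold in neither run. Of 17 members 4 rose and 6 fell (camera adjusted p = 0.470), and of 16 members 3 rose and 6 fell (0.185). MTHFD2 rose by 2.15 in H146 and by 1.58 in H524, whereas PSAT1 fell by 2.05 and 0.75. Neither a lower level of the synaptic genes nor a higher level of the amino acid starvation genes was decided, and the latter leaned lower.

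The names of the siPRL columns carry a number whose meaning is not stated: 91, 84, 83, 81 and 71 for H146 replicates A to E and 80, 76, 70, 68 and 65 for H524. On the arrays PRL was lower by 86.1%, 87.0%, 88.3%, 88.5% and 67.2% in H146 and by 79.2%, 68.4%, 71.2%, 78.9% and 72.6% in H524.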
